A study of Mus musculus with 22 samples.

How the data were processed

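RNA sequencing was done on mouse cells that carry Col2.3GFP, a reporter in which a fragment of the type I collagen promoter drives green fluorescent protein in osteoblast-lineage cells. The labels place 22 samples in 8 groups. Those analysed were undifferentiated embryonic stem cells (ESC, 3 samples), osteoblast cultures grown from them (ESC-OB, 3), GFP-positive cells sorted from such cultures (sorted ESC-OB GFP+, 3), undifferentiated induced pluripotent stem cells (iPSC, 2) and osteoblast cultures grown from the iPSC (iPSC-OB, 2). Primary calvarial osteoblasts (3) and bone cells with high or low GFP signal (3 each) were not analysed here, because none of the 3 tables holds a comparison of them. Per the labels' protocols, embryoid bodies were formed for 6 days with 0.1 µM retinoic acid from day 3 to day 5, and osteogenic medium followed until 35 to 40 days of differentiation. The labels give passages 20 to 30 for ESC and ESC-OB, passages 10 to 20 for iPSC and iPSC-OB, and no passage for the sorted cells. The stem cells were kept either on mouse embryonic fibroblast feeders or in a serum-free feeder-free medium, and the withdrawn supplements were the cytokine LIF, PD0325901, a MEK inhibitor, and CHIR99021, a GSK3 inhibitor. Libraries were made from messenger RNA with one kit, or with an ultra-low-input kit where RNA was scarce. Which samples had which medium or kit is not given in the sources used here, nor whether replicates came from separate cultures, so the p-values measure the spread between these samples only.

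The files hold the authors' own comparisons and no values per sample. The submitters' processing notes name STAR 2.4.2a, the mouse build mm9, DESeq2 and R 3.2.2, with no roles, design formula or filters, and the tables have the column names that DESeq2 gives the authors' results. Per the file headers, each gene has a base mean (a signal: the mean over the libraries of the authors' fit of counts divided by size factors), a log2 fold change with its standard error on the log2 scale, a test score (the statistic), a p-value and an adjusted p-value. The score equals the fold change divided by its standard error for every gene, within rounding. The direction of the fold changes is not stated in the authors' tables and was read from the values: Pou5f1, Nanog and Esrrb, which mark pluripotent cells, are strongly negative in all 3 deposited log2 columns, so a positive value was taken as higher in the differentiated cells. Each of both ESC tables held 19781 genes and the iPSC table held 19057, of which 18632 were shared. The ESC tables have identical base means, so they came from 1 fit and share their ESC libraries. The ESC and iPSC tables were normalised separately. An adjusted p-value was missing for 1573 genes (ESC-OB), 1193 (sorted GFP+) and 1478 (iPSC-OB) that the authors' filter left out, and such genes were never counted as changed. Benjamini-Hochberg adjustment of the deposited p-values over the other genes gave the deposited adjusted p-value for each gene. Standard errors level off at 1.89, 1.89 and 1.29, as they do when fold changes are shrunk towards 0, so folds of genes with few reads are understated, and more so in the iPSC table. Columns of values per single sample numbered 0, so no count test, other normalisation, replicate check or paired fit could be run.

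The depth was read from the lowest base means. Genes with a handful of reads have base means that are sums of whole multiples of the value of 1 read in each library. A set of such values explained all 2040 base means under 1 in the ESC fit with 9 libraries and all 1456 in the iPSC fit with 5 (absolute tolerance 3.0e-07). Of base means under 0.5 shifted slightly on purpose, 0% were explained, against 100% of the unshifted ones. Higher base means were not checked by such a shift. Simulated fits with 9 and 5 libraries gave back all 9 and 5 values. A library's side was read from the sign of the folds of genes whose reads lay in it alone. The shallowest ESC library had no such gene, and its side was read from genes with 1 read there and 1 in another ESC library. No library was tied to a labelled sample. Scaled by the mean total, the depths were 4.49 to 19.5 M reads for ESC, 6.72 to 11.5 M for ESC-OB, 22.4 to 30.1 M for sorted GFP+, 10.4 to 13.0 M for iPSC and 10.1 to 17.7 M for iPSC-OB. The iPSC side held 3 libraries by this reading, against 2 in the labels used here. Group levels in CPM (a total scaled to 1000000) were estimated from base means, fold changes and these numbers of libraries, leaving Rn45s out of the total. A floor of 3 reads over a group was 0.102 (ESC), 0.114 (ESC-OB), 0.0427 (sorted GFP+), 0.0886 (iPSC) and 0.116 CPM (iPSC-OB). It covers counting error only. Where a gene lay under the floor on one side, its fitted fold rests on the authors' shrinkage and is no bound, and list medians were also taken with such levels raised to the floor. Levels set across the ESC and iPSC tables carry no test.

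The 3 comparisons were not refitted: a gene was called where the authors' adjusted p-value was under 0.05. For the differences between the iPSC-OB and ESC-OB changes and between the sorted GFP+ and unsorted ESC-OB changes, 1 log2 fold change was subtracted from the other and divided by the root of the summed squared standard errors (Wald z, two-sided, with Benjamini-Hochberg adjustment). The latter is conservative, since ESC libraries are shared. Gene lists, 40 in all with 880 gene entries, were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the signed statistic with a preset inter-gene correlation of 0.01. This test asks whether a list moved relative to all other genes. An estimated correlation needs values per sample, so 0.05 was the alternative. Members were matched by symbol, with 7 older symbols. Other computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Transcript length and GC content were taken by symbol from GENCODE M21 transcripts of a later build than mm9, for 99.4% of the genes used, and no coordinates are printed.

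On simulated data, the iPSC-OB minus ESC-OB difference test over 18632 genes recovered 69 of 100 genes changed by 2 log2 units and 92 of 100 changed by 4, with 14 of 175 calls on unchanged genes. The sorted minus unsorted test over 19781 genes recovered 69 and 95 of 100, with 0 of 164 calls on unchanged genes. The list test called 75 of 80 shifted lists and 0 of 720 unshifted lists over 19700 genes of the ESC tables, and 72 of 80 and 1 of 720 over 18600 genes for the iPSC minus ESC difference. The simulated genes were independent and their lists random, so these counts do not show how often lists of correlated genes are called falsely.

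The tests, lists, alternatives and named genes were fixed before the data were examined, except where the text says otherwise. Named genes are 37 fixed marker genes, the 6 largest rises and 6 largest falls per comparison and the 6 largest differences per direction with a base mean of at least 100 and an adjusted p-value under 0.05, leaving out clones, predicted genes, Y-linked genes and Xist, and up to 4 members per list with the smallest adjusted p-values. Some of the genes chosen by these rules are not reported here. The same rule governs the differences. Rn45s, Actb, Gapdh and the histone genes were added after their values were seen. Alternatives covered stricter thresholds, fold minimums, filters on the base mean, re-centring on the median gene, and other settings of the list test.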

Results

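The data are 3 tables of differential expression made by the authors from messenger RNA sequencing of mouse pluripotent stem cells and of osteoblast cultures derived from them. The cell sources were embryonic stem cells (ESC) and induced pluripotent stem cells (iPSC), which are somatic cells returned to a pluripotent state. The labels name 3 ESC, 3 ESC-OB, 3 sorted ESC-OB GFP+, 2 iPSC and 2 iPSC-OB samples. OB stands for the osteoblast cultures, and GFP+ for cells sorted on the Col2.3GFP reporter, which marks cells with an active type I collagen promoter. In the 3 comparisons every fold change, standard error and adjusted p of a single gene is the authors', those of the differences between changes were computed from them, and levels in CPM are estimates from their table. The libraries behind the ESC fit ranged from 4.49 to 30.1 M reads and those behind the iPSC fit from 10.1 to 17.7 M, with the sorted cells the deepest (22.4 to 30.1 M).

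ESC-OB against ESC addresses which genes change when ESC are taken through embryoid bodies and osteogenic medium. The authors' deposited table has Col1a1 and Col1a2, which encode the chains of type I collagen, rising by 7.87 ± 0.32 and 11.73 ± 0.49 on the log2 scale (a standard error follows each ± sign, in the 3 comparisons the authors'; adjusted p = 8.52e-133 and 7.19e-126). Runx2, a transcription factor that osteoblasts require, rose by 7.83 ± 0.85 in the authors' deposited table, and Pth1r, the parathyroid hormone receptor, by 8.54 ± 0.44 (adjusted p = 1.25e-19 and 4.32e-83). Pou5f1 and Nanog, core factors of pluripotency, were at -8.81 ± 0.23 and -11.19 ± 0.43 in the authors' deposited table (an adjusted p listed as 0 and 1.59e-143). In all, 7022 genes rose and 5651 fell of 18208 with an adjusted p, so 55.4% of the changes were rises. The median gene with a base mean of at least 10 lay 0.19 above 0, and re-centring on it gave 50.5% rises.

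Of 22 genes for osteoblast matrix and mineralization, 15 rose, 2 fell and 5 did not pass the threshold (median log2 change 3.50, cameraPR adjusted p = 1.06e-04), and counts adjusted over the list alone were the same. Sparc, which encodes a collagen-binding matrix protein, rose by 3.71 ± 0.13 in the authors' deposited table, Col5a2, a fibrillar collagen gene, by 10.01 ± 0.49, and Ibsp, bone sialoprotein, by 4.35 ± 1.59 (adjusted p = 2.6e-185, 4.13e-90 and 0.00988). The 2 that fell in the authors' deposited table were Alpl, the alkaline phosphatase that pluripotent cells also carry, by 4.93 ± 0.69, and Spp1, osteopontin, by 1.61 ± 0.31 (adjusted p = 3.93e-12 and 4.98e-07). Osteocalcin is encoded by Bglap, which rose by 4.54 ± 1.61 at a base mean of 5.14, while its neighbour Bglap2 was at 1.33 ± 1.18 and Phospho1 at 0.49 ± 0.64 in the authors' deposited table, both short of the threshold. Bglap and Bglap2 are near-identical copies whose reads counting may split, so both are uncertain. Transcription factors of the osteoblast lineage rose in 11 of 16 cases and fell in none (median 2.85, adjusted p = 9.48e-04). Sp7 (osterix) and Dlx5 were at 1.69 ± 1.09 and 1.93 ± 1.81 in the authors' deposited table without passing. Of 14 osteocyte genes 8 rose and none fell (median 2.50, or 2.003 with levels raised to the floor of 3 reads, adjusted p = 0.00308). Pdpn, a podoplanin gene of early osteocytes, rose by 5.63 ± 0.15 and Phex by 3.73 ± 1.15, while Dmp1 (-0.47 ± 0.74) and Mepe (0.67 ± 1.79) did not pass in the authors' deposited table (adjusted p = 0.576 and 0.75). Sost, the sclerostin gene, had no adjusted p there and lay under the floor in both groups.

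Genes of the wider connective tissue programme rose as well. Of 24 tendon and fibroblast genes 22 rose and none fell (median 6.28, adjusted p = 1.17e-10), and of 28 genes for collagen processing and crosslinking 26 rose and 1 fell (median 3.41, adjusted p = 6.52e-18). Pdgfra, a receptor of mesenchymal cells, rose by 9.03 ± 0.32, Col6a1 by 10.68 ± 0.45 and Lox, the collagen-crosslinking lysyl oxidase, by 11.86 ± 0.57 in the authors' deposited table. Among 20 chondrocyte genes 13 rose and 2 fell (median 3.72, or 3.00 at the floor, adjusted p = 0.0268, or 0.0913 with a correlation of 0.05 and 0.0713 with a base mean of at least 100). Sox9, a cartilage regulator, rose by 8.78 ± 0.93 and Acan (aggrecan) by 1.08 ± 0.48, and Col2a1 (type II collagen) fell by 1.27 ± 0.34 in the authors' deposited table. Adipocyte genes rose in 9 of 14 cases (median 3.38, adjusted p = 0.0244, or 0.0699 with a correlation of 0.05 and 0.0532 with a base mean of at least 100), with Pparg, the adipocyte regulator, up by 5.78 ± 0.86 in the authors' deposited table. Of 20 genes for matrix proteases and their inhibitors 17 rose and 1 fell (median 5.29, adjusted p = 1.83e-11). Among them Ctsk, cathepsin K, rose by 8.81 ± 0.81 in the authors' deposited table, while Acp5, another osteoclast enzyme gene, fell by 1.63 ± 0.32. The 24 macrophage and osteoclast genes (13 rose, 2 fell, median 3.22, or 1.95 at the floor) did not pass as a list (adjusted p = 0.242, or 0.00624 with the log2 fold as the statistic).

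Naive pluripotency and division genes fell. Of 30 naive pluripotency genes 29 fell (median -6.30, adjusted p = 2.83e-23). Esrrb fell by 10.65 ± 0.42, Zfp42 by 7.47 ± 0.40 and Sox2 by 4.25 ± 0.18 in the authors' deposited table, and the exception was Klf4, which rose by 0.57 ± 0.15 (adjusted p = 2.02e-04). Of 13 primed pluripotency genes, which mark the state after implantation, 9 fell and 2 rose, and the list did not pass (median -2.49, adjusted p = 0.0737, or 6.06e-04 with the log2 fold as the statistic and 0.0364 on ranks). All 35 cell cycle and division genes fell (median -3.48, adjusted p = 1.48e-30), Mki67, a proliferation marker, by 2.81 ± 0.17 in the authors' deposited table, and 11 of 13 cell cycle inhibitors rose, Cdkn1a by 1.85 ± 0.18. All 12 genes of the 2C-like state, a rare state of stem cells in culture, fell (median -4.91, or -4.67 at the floor, adjusted p = 0.00107), and 14 of 20 germ cell genes fell with none rising (median -3.19, adjusted p = 2.73e-04). The largest falls in the authors' deposited table were those of Lefty2 (-13.43 ± 1.20), Tdh (-12.95 ± 0.82), Mcf2 (-12.86 ± 1.29), Gdf3 (-12.40 ± 1.34), Tcl1 (-12.34 ± 1.34) and Hormad1 (-11.76 ± 1.31), all under the floor in ESC-OB.

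Markers of other tissues rose beside the osteoblast genes. Cardiac muscle genes rose in 21 of 22 cases (median 5.31, adjusted p = 1.56e-07), with the troponin gene Tnnt2 up by 7.56 ± 0.45 in the authors' deposited table. Smooth muscle and pericyte genes rose in 14 of 16 (median 5.89, adjusted p = 3.72e-05), endoderm and liver genes in 22 of 25 (median 5.95, adjusted p = 1.46e-06), and epithelial genes in 20 of 24 (median 4.86, adjusted p = 1.24e-11). Krt8 and Krt18, keratins of simple epithelia, rose by 7.15 ± 0.19 and 6.97 ± 0.20, and Afp (alpha-fetoprotein) by 4.79 ± 1.15 in the authors' deposited table, and Epcam was at -0.09 ± 0.21 (adjusted p = 0.727). Endothelial genes rose in 13 of 20 cases (median 3.61, adjusted p = 0.0244, or 0.087 with a correlation of 0.05), although Pecam1, which ESC also express, fell by 5.44 ± 0.37 in the authors' deposited table. The neural list did not pass (12 rose, 8 fell of 30, adjusted p = 0.78), and Tubb3, a neuronal tubulin, fell by 3.996 ± 0.349 in the authors' deposited table. The largest rises there were C3 (13.65 ± 0.77), Krt6a (12.63 ± 1.07), Cyp2f2 (12.30 ± 0.86), Dcn (12.17 ± 1.02), Ltf (11.93 ± 0.84) and Lox, genes of complement, keratin, airway oxidation, proteoglycan and lactoferrin. Krt6a, Cyp2f2, Dcn and Ltf, like Sox9, Pparg, Bglap and Dlx5, lay under the floor of 0.102 CPM in ESC.

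Signalling genes of the culture steps rose too. BMP and TGF-beta signaling genes rose in 33 of 34 cases (median 3.88, adjusted p = 8.63e-12) and retinoic acid response genes in 15 of 17 (median 3.13, adjusted p = 6.57e-05). All 18 immediate early genes, which cells switch on within minutes of a stimulus or of handling, rose (median 5.53, adjusted p = 1.08e-32), Jun by 7.08 ± 0.20 and Fos by 9.22 ± 0.29 in the authors' deposited table. Of 18 MEK-ERK target genes 12 rose and 3 fell (median 2.68, adjusted p = 0.00346), and of 20 interferon response genes 19 rose (median 5.35, adjusted p = 1.56e-07). Ribosomal protein genes fell in 27 of 30 cases by a median of -0.93 (adjusted p = 7.4e-04) and oxidative phosphorylation genes in 22 of 25 by -0.76 (adjusted p = 3.51e-04). With a correlation of 0.05 the neural crest and cilia lists also lost their call (adjusted p = 0.108 and 0.0554).

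**Figure D1:**
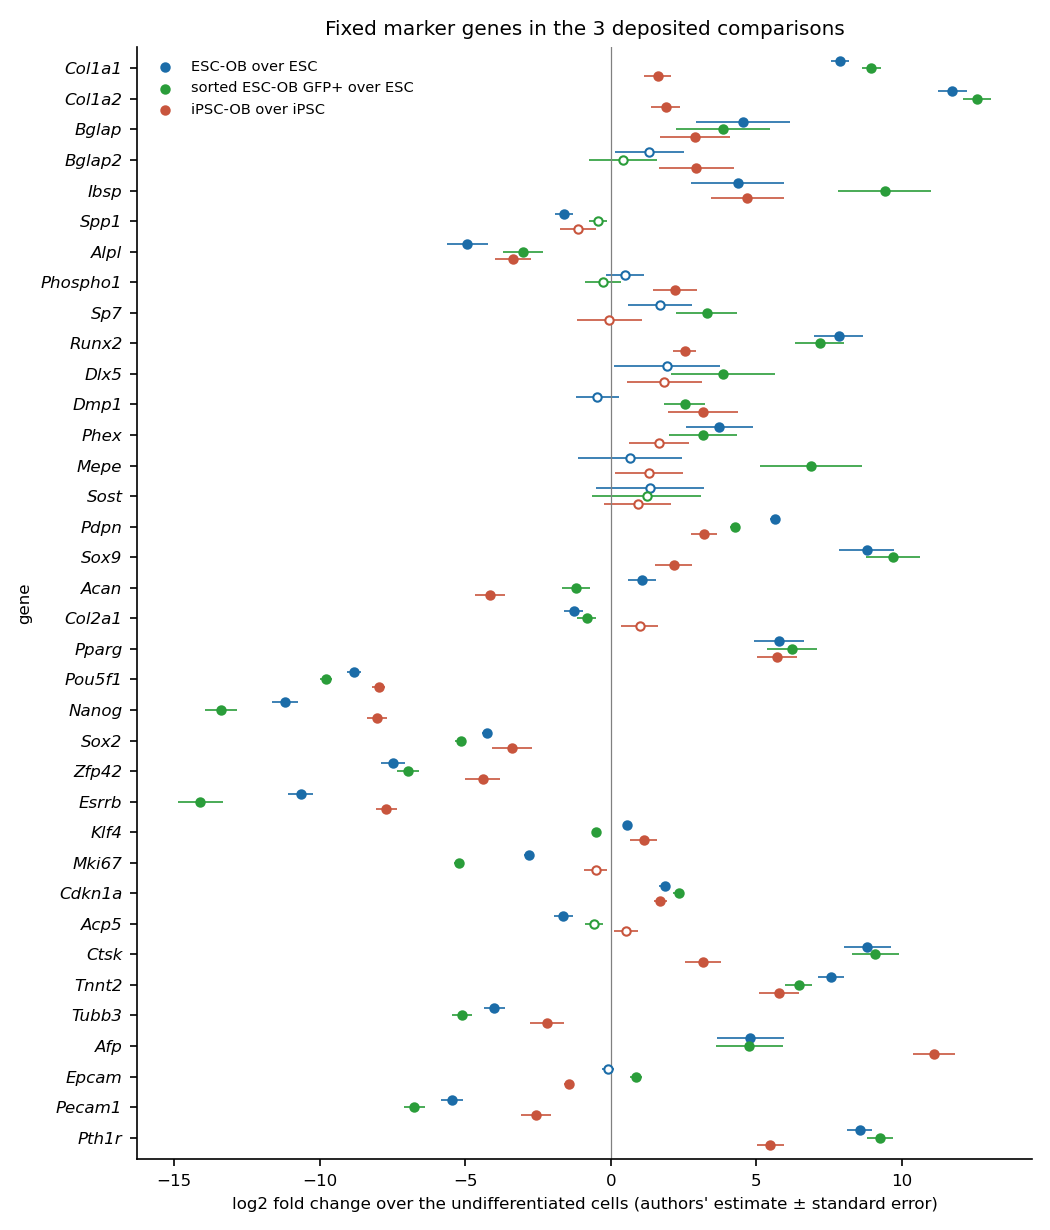
Log2 fold change of fixed marker genes over the undifferentiated cells (horizontal axis) in the 3 comparisons, from the authors' deposited table; bars are the authors' standard errors and open points did not pass an adjusted p of 0.05. Col1a2 stands at 11.73 in ESC-OB, 12.58 in sorted GFP+ cells and 1.89 in iPSC-OB, and Pou5f1 at -8.81, -9.78 and -7.97.

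Sorted ESC-OB GFP+ against ESC addresses the same change in the cells with an active collagen reporter. Col1a1 rose by 8.95 ± 0.32 and Col1a2 by 12.58 ± 0.49 in the authors' deposited table (adjusted p = 4.25e-172 and 3.87e-145), Ibsp by 9.41 ± 1.59, and the osteocyte genes Dmp1 and Mepe by 2.53 ± 0.70 and 6.88 ± 1.74 (adjusted p = 8.14e-09, 5.77e-04 and 1.49e-04). Sp7 rose by 3.29 ± 1.05 and Dlx5 by 3.85 ± 1.78 in the authors' deposited table (adjusted p = 0.00293 and 0.0435). Alpl fell by 3.02 ± 0.69, and Spp1 (-0.44 ± 0.31), Phospho1 (-0.27 ± 0.62) and Bglap2 (0.42 ± 1.17) did not pass in the authors' deposited table. Mki67 fell by 5.21 ± 0.17 and Nanog by 13.39 ± 0.54 there. Of 18588 genes with an adjusted p, 7273 rose and 6018 fell, and the median gene lay at 0.21.

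Osteoblast matrix genes rose in 17 of 22 cases and fell in 1 (median 4.41, adjusted p = 4.84e-05, 18 and 1 when adjusted over the list alone). Osteoblast transcription factors rose in 13 of 16 cases (median 3.86, adjusted p = 0.00251) and osteocyte genes in 12 of 14 (median 3.46, or 2.96 at the floor, adjusted p = 0.00275). Runx2 rose by 7.17 ± 0.85, Pdpn by 4.26 ± 0.15, Phex by 3.17 ± 1.15 and Bglap by 3.85 ± 1.60 in the authors' deposited table, and Sost (1.24 ± 1.87) did not pass. Tendon and fibroblast genes rose in 21 of 24 cases and fell in 2 (median 6.59, or 5.51 at the floor, adjusted p = 9.84e-08), and collagen processing genes rose in 26 of 28 (median 3.50, adjusted p = 1.3e-13). Of 20 chondrocyte genes 13 rose and 2 fell (median 4.02, or 3.22 at the floor, adjusted p = 0.0353, or 0.111 with a correlation of 0.05 and 0.0773 with a base mean of at least 100). Acan and Col2a1, cartilage matrix genes, fell by 1.20 ± 0.48 and 0.83 ± 0.33 in the authors' deposited table.

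All but 1 of the 30 naive pluripotency genes fell (median -7.21, adjusted p = 7.37e-24), with Klf4 down by 0.51 ± 0.15 in the authors' deposited table. All 35 division genes fell (median -3.35, adjusted p = 9.93e-25). Epithelial genes rose in 21 of 24 cases (median 6.29, adjusted p = 1.94e-13), Epcam by 0.86 ± 0.21 in the authors' deposited table, endoderm genes in 21 of 25 (median 5.96, adjusted p = 2.16e-05), and cardiac genes in 19 of 22 (median 3.96, adjusted p = 0.00225). Tubb3 and Pecam1 fell by 5.13 ± 0.34 and 6.75 ± 0.37 in the authors' deposited table, against the rises of other tissue markers, and Acp5 (-0.58 ± 0.31) did not pass. All 18 immediate early genes rose (median 6.79, adjusted p = 6.95e-39). The ribosomal protein genes fell in 27 of 30 cases (median -1.99, adjusted p = 1.42e-09), and Rn45s, the gene of the ribosomal RNA precursor, fell by 4.13 ± 0.31 in the authors' deposited table. The Rn45s value cannot tell reads of the precursor from reads of mature ribosomal RNA. The largest rises there were Cyp2f2 (13.52 ± 0.86), Dcn (13.24 ± 1.02), Ctla2a (13.19 ± 1.01), Krt6a (13.19 ± 1.07), C3 (13.15 ± 0.77) and Bpifa1 (13.01 ± 1.03), and the largest falls Tdh (-14.80 ± 0.92), Esrrb (-14.10 ± 0.77), Fgf4 (-13.85 ± 1.17), Gdf3 (-13.51 ± 1.24), Tcl1 (-13.44 ± 1.24) and Nanog. Of these, all risers except C3 lay under the floor in ESC, and Tdh, Fgf4, Gdf3 and Tcl1 under that of the sorted cells, 0.0427 CPM.

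The difference between the sorted GFP+ and unsorted ESC-OB changes addresses what the sort on the reporter selects. Among fixed osteoblast and osteocyte genes, Dmp1 was 3.00 ± 1.02 log2 units higher and Spp1 1.18 ± 0.44 higher in the sorted change (adjusted p = 0.0173 and 0.0341), and Pdpn (-1.37 ± 0.21) was lower. Col1a1 (1.08 ± 0.45), Ibsp (5.05 ± 2.25) and Mepe (6.21 ± 2.50) had positive differences that did not pass (adjusted p = 0.0663, 0.0931 and 0.0556). Mki67 was at -2.396 ± 0.236, Nanog at -2.20 ± 0.70, Pou5f1 at -0.97 ± 0.31, Sox2 at -0.90 ± 0.26, Esrrb at -3.45 ± 0.88, Klf4 at -1.08 ± 0.21 and Acan at -2.27 ± 0.68, all past the test, while Epcam was 0.95 ± 0.30 higher. In all 2107 differences were positive and 2392 negative (4499 of 19781 genes). Of the 35 division genes 4 were higher and 3 lower, with a median of 0.11 (adjusted p = 0.982).

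Of the 40 lists 5 differed between the sorted and unsorted change. Ribosomal protein genes were lower in 25 of 30 cases (median -1.10, adjusted p = 2.51e-10) and immediate early genes higher in 11 of 18 (median 1.09, adjusted p = 6.3e-07). Oxidative phosphorylation genes were higher in 9 of 25 (13 when adjusted over the list alone; median 0.44, adjusted p = 0.00418), epithelial genes higher in 8 and lower in 1 of 24 (median 0.99, adjusted p = 0.0191), and cardiac genes lower in 8 of 22 (median -1.22, adjusted p = 0.014). The last 3 calls were lost with a correlation of 0.05 (adjusted p = 0.0907, 0.173 and 0.141), the first also with the log2 fold as the statistic (0.159) and the others with a base mean of at least 100 (0.101 and 0.17). The osteoblast matrix list, with 1 gene higher and 1 lower of 22 (median 0.92), and the osteocyte list, with 2 higher and 1 lower of 14 (median 0.98), did not pass (adjusted p = 0.48 and 0.748), but both did with the log2 fold as the statistic (adjusted p = 0.00289 and 0.00579), so whether they were higher as lists depends on the statistic. That setting also called the 2C-like, neural and trophoblast lists, all lower in the sorted change (adjusted p = 2.38e-14, 9.25e-06 and 0.00429, against 0.11, 0.26 and 0.714), the first and second also on ranks (0.0265 and 0.00491). Of 12 genes in the 2C-like list, 11 lay under the floor on a side of the sorted comparison and 6 on a side of the unsorted one. Its calls therefore rest largely on shrunken folds. The largest positive differences were Krt42 (4.17 ± 0.75), Cebpb (3.55 ± 0.42), Hist1h2ac (2.84 ± 0.41), Hist1h2ag (2.70 ± 0.28), Zbed5 (2.43 ± 0.21) and Rgcc (2.305 ± 0.606). On the negative side stood Zscan4f (-6.94 ± 1.21), Zscan4c (-6.89 ± 1.21), Zscan4e (-6.77 ± 1.24), Zscan4b (-6.43 ± 1.25) and Zscan4a (-6.08 ± 1.27). The Zscan4 genes are near-identical copies that mark the 2C-like state, their reads may be shared, and all 5 lay under the floor in the sorted cells, so their differences rest on shrunken folds. Rn45s differed by -4.40 ± 0.44 (adjusted p = 2.94e-21). Across 14654 genes the difference fell with transcript length (Spearman rho -0.481, across genes, which are not independent replicates), from a median of 0.63 in the 1466 genes with the shortest transcripts to -1.01 in the 1466 with the longest. The list and gene values above are not corrected for this trend. The oxidative phosphorylation median of 0.44 was no higher than that of the shortest genes, so the trend may account for it.

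**Figure D2:**
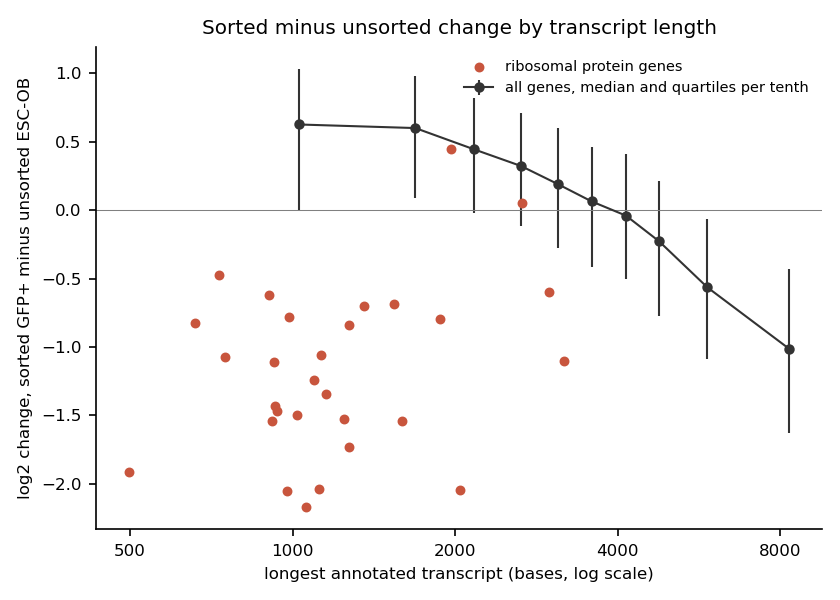
Sorted minus unsorted log2 change (vertical axis) against the longest annotated transcript of each gene in bases (log axis). Dark points are medians of 10 groups of genes of rising length with quartile bars, from 0.63 to -1.01, and red points are 29 ribosomal protein genes, most of which lie below the dark points.

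iPSC-OB against iPSC addresses whether the second cell source follows the same course. Col1a1 rose by 1.62 ± 0.46 and Col1a2 by 1.89 ± 0.49 in the authors' deposited table (adjusted p = 0.00144 and 4.51e-04), Sparc by 4.84 ± 0.52 and Ibsp by 4.69 ± 1.26. Afp, a product of yolk sac and fetal liver, had the largest rise there (11.11 ± 0.72, adjusted p = 1.07e-50). Runx2 rose by 2.54 ± 0.40 in the authors' deposited table, while Sp7 was at -0.05 ± 1.13 (adjusted p = 0.977). Pou5f1 fell by 7.97 ± 0.23, Nanog by 8.04 ± 0.34 and Esrrb by 7.71 ± 0.36 in the authors' deposited table. Of 17579 genes with an adjusted p, 4596 rose and 4053 fell in iPSC-OB against iPSC, and the median gene lay at 0.06.

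Osteoblast matrix genes rose in 16 of 22 cases and fell in 1 (median 1.80, adjusted p = 0.00559, 17 and 1 when adjusted over the list alone). Mgp, a matrix inhibitor of calcification, rose by 3.97 ± 0.41, Bglap by 2.89 ± 1.21, Bglap2 by 2.93 ± 1.29 and Phospho1 by 2.20 ± 0.76, and Alpl fell by 3.35 ± 0.61 in the authors' deposited table. Spp1 was at -1.13 ± 0.62 (adjusted p = 0.12) in the authors' deposited table. The osteoblast transcription factors did not pass as a list (6 rose, 1 fell of 16, median 1.12, adjusted p = 0.128), and Dlx5 was at 1.83 ± 1.29 in the authors' deposited table. Osteocyte genes rose in 6 of 14 cases and fell in 1 (median 1.27, adjusted p = 0.0444, or 0.107 with a correlation of 0.05, 0.06 with the log2 fold as the statistic and 0.0538 with a base mean of at least 10). Pdpn rose by 3.199 ± 0.440 and Dmp1 by 3.18 ± 1.20 in the authors' deposited table, and Phex (1.65 ± 1.02), Mepe (1.32 ± 1.16) and Sost (0.92 ± 1.15) did not pass. Tendon and fibroblast genes rose in 16 of 24 cases (median 2.11, adjusted p = 4.35e-10) and collagen processing genes in 26 of 28 (median 2.15, adjusted p = 3.59e-09). Adipocyte genes rose in 10 of 15 cases (median 3.96, adjusted p = 6.51e-05), Pparg by 5.70 ± 0.69 in the authors' deposited table. The chondrocyte list did not pass (10 rose, 2 fell of 19, adjusted p = 0.12, or 0.00682 with the log2 fold as the statistic): Sox9 rose by 2.17 ± 0.64, Acan fell by 4.15 ± 0.52 and Col2a1 was at 1.00 ± 0.63 in the authors' deposited table. Pth1r rose by 5.47 ± 0.47 and Ctsk by 3.17 ± 0.62 there, and Acp5 was at 0.52 ± 0.42.

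Naive pluripotency genes fell in 25 of 30 cases (median -4.54, adjusted p = 5.76e-43), with Klf4 up by 1.13 ± 0.47 in the authors' deposited table. Primed pluripotency genes fell in 11 of 13 (median -3.84, adjusted p = 4.93e-09), with Dnmt3b at -4.90 ± 0.25 in the authors' deposited table. Division genes fell in 27 of 35 cases (median -1.21, adjusted p = 2.54e-12), but Mki67 was at -0.52 ± 0.39 (adjusted p = 0.277) in the authors' deposited table, and all 13 cell cycle inhibitors rose (median 1.78, adjusted p = 2.21e-04). All 25 endoderm and liver genes rose (median 6.05, adjusted p = 3.27e-26), and the 6 largest rises in the authors' deposited table after Afp included Aqp8 (10.64 ± 0.90), the haptoglobin gene Hp (10.08 ± 0.93), the fibrinogen gene Fgb (9.98 ± 0.93), Fmo2 (9.92 ± 0.93) and Psca (9.91 ± 0.93). Cardiac genes rose in 18 of 21 (median 3.76, adjusted p = 4.23e-09), Tnnt2 by 5.78 ± 0.69 in the authors' deposited table. Epithelial genes rose in 11 and fell in 5 of 24 (median 0.77, adjusted p = 0.00559, or 0.0693 on ranks), and Epcam fell by 1.44 ± 0.17 in the authors' deposited table. Tubb3 and Pecam1 fell there by 2.20 ± 0.57 and 2.56 ± 0.51. Of 18 immediate early genes 2 rose and 7 fell (median -0.29, adjusted p = 0.00542, lost on ranks with adjusted p = 0.144 and with a base mean of at least 100 with 0.0675), Fosb by 5.06 ± 0.28 in the authors' deposited table. MEK-ERK targets fell in 12 of 18 cases and rose in 2 (median -1.23, adjusted p = 2.96e-04). The largest falls in the authors' deposited table were Rbmxl2 (-9.01 ± 0.90), Tdgf1 (-8.93 ± 0.38), Rex2 (-8.73 ± 0.36), Zfp600 (-8.71 ± 0.46), Lefty2 (-8.62 ± 0.36) and Pla2g1b (-8.52 ± 0.79). Rbmxl2 and Pla2g1b lay under the floor in iPSC-OB, and Bglap2 under that in iPSC.

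**Figure D3:**
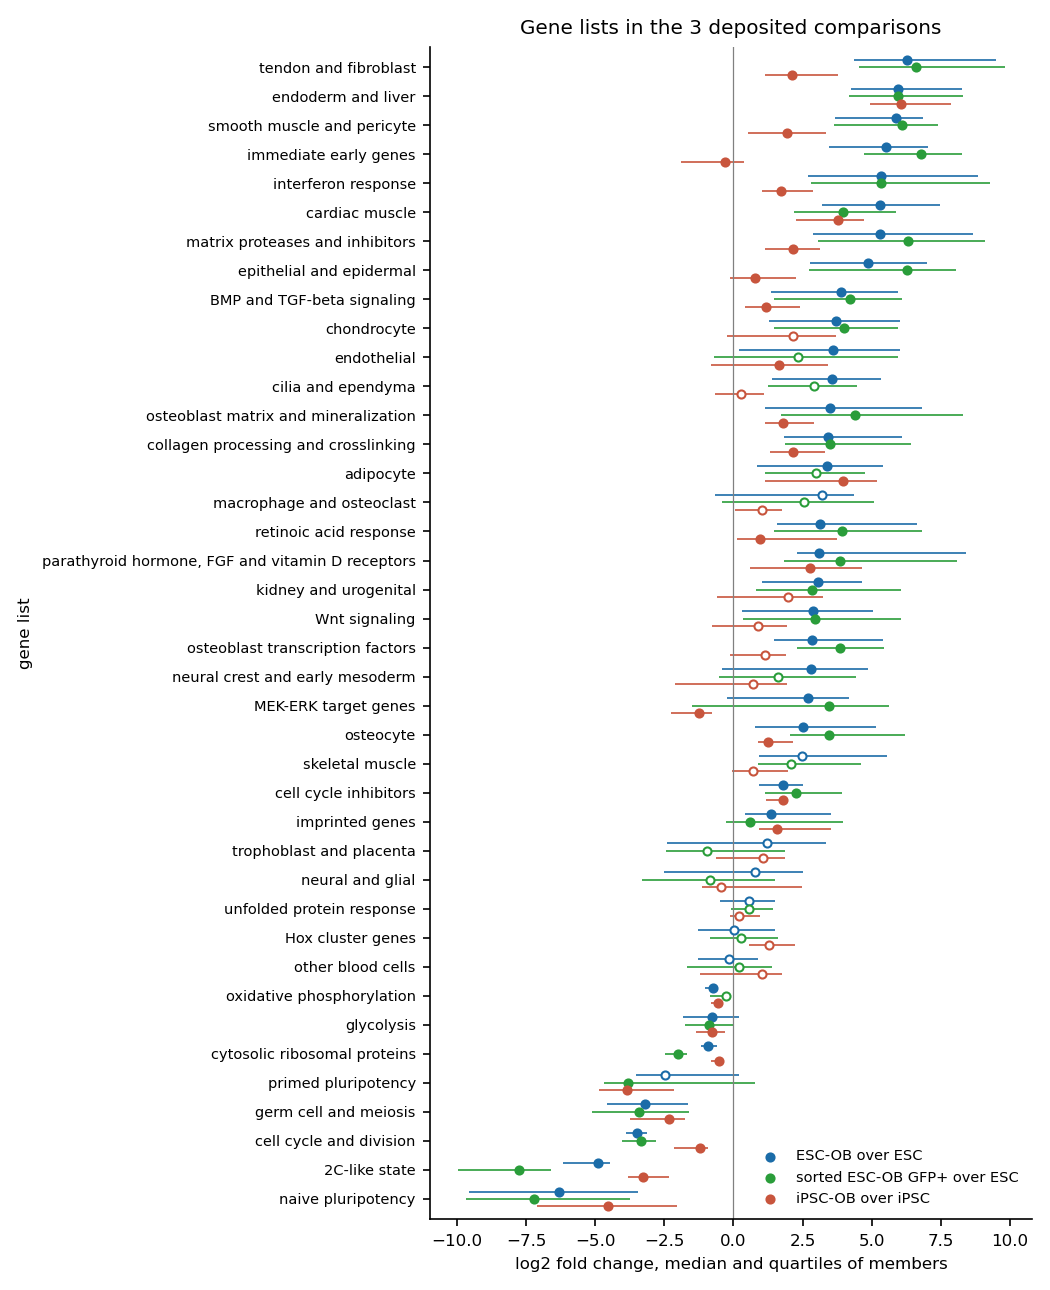
Median log2 fold change of each of the 40 gene lists (points) with the quartiles of its members (lines) in the 3 comparisons, and open points where cameraPR gave an adjusted p of 0.05 or more. The immediate early genes stand at 5.53 and 6.79 in the ESC tables and at -0.29 in the iPSC table, and the endoderm list at 5.95, 5.96 and 6.05.

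The difference between the iPSC-OB and ESC-OB changes addresses whether the course of differentiation differed between the ESC and iPSC cultures. Passage differed with the cell source (20 to 30 for ESC, 10 to 20 for iPSC), so the effects of passage and source cannot be told apart. The collagen genes rose less in the iPSC comparison: the difference, iPSC-OB change minus ESC-OB change, was -6.25 ± 0.56 for Col1a1 and -9.84 ± 0.69 for Col1a2 (adjusted p = 1.53e-26 and 9.18e-43). Fosb, Egr1 and Fos, immediate early genes, had differences of -14.93 ± 0.53, -14.39 ± 0.42 and -11.41 ± 0.36. Mki67 fell less (2.29 ± 0.43) and Afp rose more (6.32 ± 1.36) in iPSC-OB. In all 5249 of 18632 genes differed, 2050 with a positive and 3199 with a negative difference, and the positive share of 39.1% became 46.9% after each comparison was re-centred on its median gene. Of 22 osteoblast matrix genes 9 had a negative and none a positive difference (median -1.36, adjusted p = 7.41e-04, lost on ranks with adjusted p = 0.0976), and of 24 fibroblast genes 19 were negative (median -4.58, adjusted p = 1.46e-13). Of the 35 division genes 32 were positive (median 2.19, adjusted p = 2.46e-19) and all 18 immediate early genes were negative (median -5.77, adjusted p = 4.59e-112). The iPSC and ESC groups also differed before differentiation: the estimated level of Col1a1 was 405 CPM in iPSC and 10.3 in ESC, and 1283 in iPSC-OB and 2587 in ESC-OB, from tables normalised separately and without a test. Fold changes were shrunk more in the iPSC table.

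**Figure D4:**
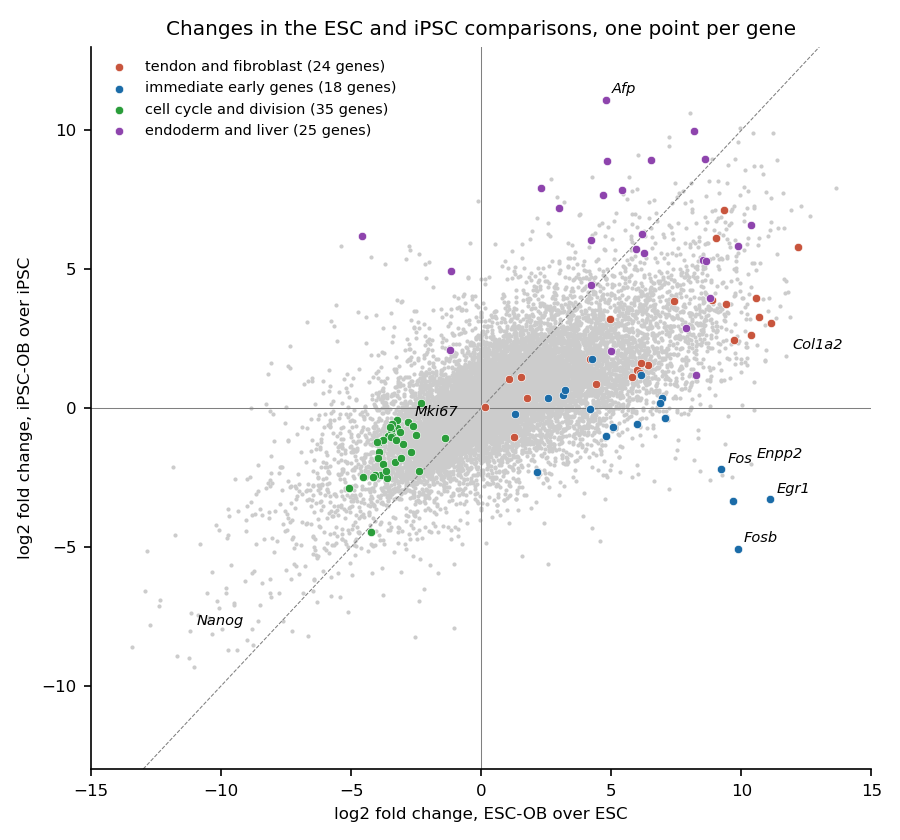
Log2 fold change in iPSC-OB over iPSC (vertical axis) against ESC-OB over ESC (horizontal axis), 1 grey point for each of 18632 genes, with 4 gene lists coloured and the line of equal change dashed. Egr1, Fos and Fosb lie at the lower right, and most endoderm genes lie above 0 on both axes.

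Across 18632 genes the ESC-OB and iPSC-OB changes had a Pearson r of 0.70 (Spearman rho 0.69) and the same sign in 77.3%. These comparisons share no library. Of 17139 genes tested in both, 3804 rose in both, against 1804 for independent lists of those sizes, and 3291 fell in both, against 1306, while 223 rose in ESC-OB and fell in iPSC-OB and 153 did the opposite. The ESC-OB and sorted GFP+ changes, which share the ESC libraries, had an r of 0.92 and the same sign in 83.3% of 19781 genes. Unchanged groups simulated against shared controls gave an r of 0.48 and 66.0%, and a covariance of 0.38 against the observed 7.86, a difference of 7.48. Of 18208 genes 5921 rose in both, against 2805 for independent lists, and 4689 fell in both, against 1868. The ESC libraries could not be split without values per sample, so part of this excess may come from the shared controls. By the standard errors, shared controls alone could give a covariance of at most 0.76, far below the observed 7.86. The sorted GFP+ and iPSC-OB changes had an r of 0.65 and the same sign in 73.1%. Genes are not independent replicates, and no p is given across them.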

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

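The tests of shrinkage in the fibroblast list, of fibroblast levels in the undifferentiated cells, of MEK-ERK target levels in all groups, of transcript length and of the share of dividing cells were chosen after the results were seen. What marked each result in this part is a tested difference between groups: the change from iPSC to iPSC-OB differed from the change from ESC to ESC-OB (Wald z, adjusted p under 0.05). Values are the iPSC-OB change minus the ESC-OB change on the log2 scale. In all 5249 genes differed.

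Among osteoblast, osteocyte and cartilage genes the differences were -6.25 for Col1a1, -9.84 for Col1a2, -5.29 for Runx2, -2.43 for Pdpn, -6.62 for Sox9, -5.22 for Acan and -3.07 for Pth1r, against 3.65 for Dmp1 and 2.27 for Col2a1. Ctsk and Acp5, osteoclast enzyme genes, differed by -5.64 and 2.15. Pluripotency genes had fallen less in iPSC-OB: Pou5f1 by 0.84, Nanog by 3.15, Zfp42 by 3.07 and Esrrb by 2.94, and so had the proliferation marker Mki67, by 2.29. Markers of other tissues differed by 6.32 (Afp), 1.80 (Tubb3), 2.88 (Pecam1) and -1.36 (Epcam). The largest positive differences beside Afp were those of Xlr3a (8.89), Inpp5d (8.01), Tdh (6.37), Galnt6 (6.26) and Foxh1 (6.00), and the largest negative ones those of Fosb (-14.93), Egr1 (-14.39), Enpp2 (-12.38), Fos (-11.41), Gbp2b (-11.39) and Psmb8 (-10.69). Tdh and Foxh1 lay under the floor in ESC-OB, and Sox9, Enpp2, Gbp2b and Psmb8 under that in ESC, so their differences rest on shrunken folds.

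List medians were lower in the iPSC comparison for osteoblast matrix genes (-1.36), osteoblast transcription factors (-1.98), tendon and fibroblast (-4.58), collagen processing (-1.25), primed pluripotency (-1.44), neural crest (-2.49), smooth muscle (-2.86), epithelial (-3.56) and kidney genes (-2.08). The same held for signalling and response lists: retinoic acid (-1.60), BMP and TGF-beta (-2.42), Wnt (-2.27), MEK-ERK targets (-3.21), receptors for parathyroid hormone, FGF and vitamin D (-1.97), matrix proteases (-3.88), immediate early genes (-5.77), interferon response (-3.65) and cilia (-3.07). Medians were higher for naive pluripotency (2.08), cell cycle and division (2.19), germ cell (1.48) and ribosomal protein genes (0.27). Of these, the primed pluripotency, neural crest, kidney, germ cell and ribosomal calls were lost with a correlation of 0.05, and the osteoblast matrix call on ranks (adjusted p = 0.0976).

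For the first pattern weighed, the smaller rise of collagen and fibroblast genes in the iPSC comparison, stronger shrinkage in the iPSC fit is argued against as the whole cause, since the median of the 24 fibroblast genes stayed at -5.48 (-7.89 to -2.83, bootstrap over genes) with the shrinkage undone. The median iPSC to ESC ratio of these genes was 10.5 (4.89 to 36.6), against 0.873 for division genes and 1.09 for ribosomal proteins, so a higher starting level in iPSC could account for much of the pattern. Ratios of levels here and below were taken with levels under the floor raised to it, while the CPM values are as estimated. Fibroblast-type cells among the iPSC, such as feeders or cells left from reprogramming, cannot be told apart from another state of the iPSC, because abundant fibroblast genes were not all raised alike. In estimated CPM, iPSC against ESC, Col1a1 was at 405 and 10.3, Col1a2 at 314 and 0.669, Col12a1 at 82.7 and 0.878 and Col6a1 at 39.5 and 0.515. Also raised were Col6a3 (87.8 and 0.430), Col6a2 (24.8 and 0.160), Postn (28.5 and 0.222) and Col3a1 (65.0 and 1.09). Dcn (1.92 and 0.0643) and Pdgfra (8.16 and 1.04) were 18.9 and 7.87 times higher in iPSC but stayed low there, the Dcn ratio with its ESC level raised to the floor. Lum (0.314 and 0.233) and Pdgfrb (17.2 and 5.92) were raised less, by 1.35 and 2.91 times. Sparc (332 and 538), which is outside the fibroblast list, was not higher. No list gene was shared with another list (0 of 24), the iPSC were not sorted, and the ratio was also high for the macrophage (7.92), matrix protease (7.43), primed pluripotency (6.02), osteoblast transcription factor (5.42), osteocyte (5.22), neural crest (3.87) and epithelial lists (3.78). Whether a lower level in iPSC-OB than in ESC-OB contributed is not decided for the 24 fibroblast genes as a set. Their median iPSC-OB to ESC-OB ratio was 0.947 (0.517 to 1.09), with 7 genes under 0.5 and 3 over 2. The interval lies above 0.5, the limit set for this cause. It also holds ratios well below equal levels, so it cannot exclude a part in the pattern. The tables were normalised separately, but ribosomal proteins stood at 1.28 by the same ratio. Spontaneous differentiation of the iPSC is not decided: endoderm, cardiac and neural genes had an iPSC to ESC ratio of 1.62 (1.20 to 2.34). They stood somewhat higher in iPSC, but by less than the fibroblast genes. A difference between the cell sources themselves, or in their passage, stays open as untested.

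The second pattern was the rise of immediate early and MEK-ERK target genes in the ESC comparison alone. A lower MEK-ERK activity in ESC than in iPSC, as under a MEK inhibitor, cannot be told apart from a wider difference between these cells. The median iPSC to ESC ratio of the 18 MEK-ERK targets was 5.34 (1.95 to 11.2), with 12 of 18 over 2 and 0 under 0.5. Dusp4 stood at 22.2 and Dusp6 at 15.2, while Etv5 (566 CPM in iPSC and 538 in ESC) and Spred2 (65.2 and 40.6) differed less. However, 6 of the other 39 lists had a higher median ratio, among them the fibroblast (10.5), macrophage (7.92) and matrix protease lists (7.43). The immediate early genes (7.36) were also higher, but they are part of this pattern and share Egr1 with the targets, so they do not count against it. The labels used here do not say which medium each sample had. A GSK3 inhibitor in the ESC medium cannot be told apart from none, since the ratio of 6 beta-catenin targets was 1.80 (0.243 to 6.55), from 0.235 for Cdx1 and 0.2503 for Notum to 6.62 for Nkd1. For the immediate early genes the median iPSC-OB to ESC-OB ratio was 0.0998 (0.0685 to 0.290), the lowest of the lists ahead of cilia (0.165) and interferon response genes (0.253). A handling response in ESC-OB needs such a low ratio. It does not single out handling, because the pattern was chosen from the same tables and other differences between the cultures would give it too. The MEK-ERK targets were also lower in iPSC-OB, with a ratio of 0.655 (0.417 to 0.888) and 5 of 18 under 0.5. Their median lay above 0.5, the limit set for a handling response, and its interval spans that limit, so this ratio cannot decide. Egr1 was at 0.720, 1717, 228 and 24.5 CPM in ESC, ESC-OB, iPSC and iPSC-OB, so both ends of the comparison differed. Biological differences between the cell sources, and their difference in passage, stay open as untested.

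The last pattern, chosen after its values were seen, was the lower Rn45s (-4.40 ± 0.44) and ribosomal protein genes in the sorted than in the unsorted change. Transcript length and GC bias is argued against as the whole cause, since 29 ribosomal protein genes stayed at -1.90 (-2.11 to -1.43) after both trends were removed, from -1.11 before, and the trends alone would have raised them (median 0.60). A lower share of dividing cells is not decided, since the median difference of the 35 division genes lay only a little below 0 with the same trends removed (-0.15, -0.36 to -0.02). Before the trends were removed it was 0.11, and the members went both ways. Mki67 (-2.396 ± 0.236), Top2a (-1.69 ± 0.28) and Kif11 (-1.20 ± 0.35) were lower and 4 others higher. These values of single genes are not corrected for length or GC content. Another library type for the sorted cells cannot be told apart from the sort, because the labels name another kit for very small amounts of RNA without saying which libraries it made. The difference followed transcript length (Spearman rho -0.481, -0.492 to -0.467), but in the direction that would raise these short genes, and Rn45s made up 0.443% of the total in sorted cells, 8.26% in unsorted cells and 6.51% in ESC. The Rn45s values cannot tell the precursor from mature ribosomal RNA left in the libraries. The sort itself and true differences in ribosome production stay open as untested.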

How the results depend on the processing

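The alternatives with shrinkage undone and with list members of a base mean of at least 100 only were chosen after the data were seen. Counts of genes in ESC-OB against ESC, sorted ESC-OB GFP+ against ESC and iPSC-OB against iPSC (12673, 13291 and 8649) stayed within 1.5 times under an adjusted p of 0.01, a log2 fold of at least 1, a base mean of at least 10, no filter and re-centring. They dropped to 6259, 7017 and 3259 with a log2 fold of at least 2, which leaves smaller changes out, and to 7907, 8804 and 3633 with Bonferroni, a stricter adjustment. The share of rises moved by over 10 percentage points only under that fold minimum, to 68.1%, 62.2% and 65.0% for the 3 in turn from 55.4%, 54.7% and 53.1% (under 10 for the sorted cells), and the cause was not tested. The count for the difference between the iPSC-OB and ESC-OB changes (5249) stayed within 1.5 times throughout, with 5176 when shrinkage was undone. That for the difference between the sorted GFP+ and unsorted ESC-OB changes (4499) became 2565, with 33.5% higher against 46.8%, for an absolute difference of at least 1, by leaving out smaller differences. It became 6988 when 0.5 of each variance was taken out for the shared ESC libraries, by a smaller error, and 4976 with shrinkage undone.

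At a base mean of at least 10 and of at least 100, the same-sign share, ESC-OB and sorted GFP+, was 86.4% and 85.3% (83.3% over all genes). The same-sign share, ESC-OB and iPSC-OB, was 80.7% and 82.7% (77.3%), and the same-sign share, sorted GFP+ and iPSC-OB, 75.03% and 75.5% (73.1%), and the cause was not tested. Of the gene lists, 5 were called for the difference between the sorted GFP+ and unsorted ESC-OB changes, 2 with a correlation of 0.05 (a wider null), 9 with the fold as the statistic and 3 with members of a base mean of at least 100, and for the last 2 settings the cause was not tested. The other list counts stayed within 1.5 times (22 to 32 in ESC-OB against ESC and sorted ESC-OB GFP+ against ESC, 23 to 28 in iPSC-OB against iPSC and 16 to 29 for the difference between the iPSC-OB and ESC-OB changes). No list and no fixed gene reversed. Of 538 alternative values of fixed genes 495 kept their side of the threshold, 42 lost their call and 1 gained it. Re-centring ended the calls of Acan (ESC-OB), Dlx5 (sorted GFP+) and Bglap2 (iPSC-OB) and gained Acp5 (sorted GFP+).

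No paired analysis was possible because the authors' tables hold no values per sample. For the same reason TMM and DESeq2 size factors, another pseudocount, the replicate block and leave-one-out were not run. Depth limits what can be said of genes near 0.102 CPM in ESC and 0.114 CPM in ESC-OB. Raising levels under the floor to it moved 32 of 120 list medians by over 0.1 and 11 by over 0.5, the most by 1.59, and changed the sign of 3 (other blood cells in both ESC comparisons and Hox genes in sorted cells), none of them called.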

Other observations

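Imprinted genes, which are read from 1 parental copy, rose as a list in all comparisons, least firmly in the sorted cells. In ESC-OB against ESC 20 of 30 rose and 3 fell (median 1.36, adjusted p = 1.12e-04), in the sorted cells 14 rose and 7 fell (median 0.58, adjusted p = 0.0165, lost with a correlation of 0.05, with the log2 fold as the statistic and on ranks, with adjusted p = 0.096, 0.0833 and 0.127), and in iPSC-OB against iPSC 20 rose and 2 fell (median 1.58, adjusted p = 6.38e-10). The growth factor gene Igf2 rose by 10.27 ± 0.42 in ESC-OB, by 8.95 ± 0.42 in sorted cells and by 4.83 ± 0.34 in iPSC-OB in the authors' deposited table, and its neighbour H19 by 8.54 ± 0.41 in ESC-OB and 4.36 ± 0.30 in iPSC-OB. Peg10, a gene of the placenta, fell by 4.48 ± 0.27 in the sorted cells in the authors' deposited table, and its difference between the sorted and unsorted changes was -5.10 ± 0.37.

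Hox genes, which set position along the body axis, did not pass as a list (adjusted p = 0.78, 0.859 and 0.0668), although 14 of 36 rose and 1 fell in iPSC-OB against iPSC, while 6 rose and 6 fell in each ESC comparison. In iPSC-OB the list did pass with the log2 fold as the statistic, with a base mean of at least 10 and on ranks (adjusted p = 0.00873, 0.024 and 0.0075). Hoxb4 rose by 2.98 ± 0.62 and Hoxb8 by 2.83 ± 0.67 in iPSC-OB, and Hoxb2, under the floor in ESC, by 6.42 ± 1.27 in ESC-OB in the authors' deposited table. Neural and glial genes did not pass either (adjusted p = 0.78, 0.311 and 0.919), except in the sorted cells with the log2 fold as the statistic (adjusted p = 0.0387). The glial genes Gfap and Aqp4, the latter under the floor in ESC, rose by 8.39 ± 0.95 and 11.16 ± 1.09 in ESC-OB and the neurofilament gene Nefh fell by 4.95 ± 0.61 in the authors' deposited table. In iPSC-OB the neural list had a median of -0.46 and a mean of 0.43, and the neural crest list a median of 0.72 and a mean of -0.26.

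Glycolysis genes fell in 14 of 20 cases in ESC-OB against ESC (median -0.78, adjusted p = 0.00753), 13 in the sorted cells (median -0.88, adjusted p = 0.0263) and 12 in iPSC-OB against iPSC (median -0.78, adjusted p = 2.14e-04). The call in the sorted cells was lost with a correlation of 0.05, with the log2 fold as the statistic and with a base mean of at least 10 or 100 (adjusted p = 0.096, 0.071, 0.052 and 0.0981), and that in ESC-OB with the fold alone (0.0595). Of the glycolysis genes Gapdh, often used as a reference gene, fell by 1.97 ± 0.18, 2.05 ± 0.18 and 1.44 ± 0.18 in the authors' deposited table. Actb, another such gene, was at -0.24 ± 0.13 (adjusted p = 0.0825), -0.87 ± 0.13 and -0.56 ± 0.18 in the authors' deposited table.

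Of 40 histone cluster genes, chosen after their values were seen, 19 were higher and none lower in the sorted than in the unsorted change (median difference 1.73), with median folds of -0.83 in sorted and -2.77 in unsorted cells. Replication-dependent histone messages mostly lack a poly(A) tail. The sorted minus unsorted difference was also higher for short transcripts in general (median 0.63 in the 1466 genes with the shortest), and the histone values are not corrected for length. The cause was not tested. The reading of single reads from the lowest base means gave 3 libraries on the iPSC side of the fit, while the labels used here name 2 iPSC samples.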
